A study of Mus musculus with 12 samples.

How the data were processed

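RNA of 12 cultures of mouse bone-marrow-derived macrophages was profiled, 3 for each combination of genotype (WT or Trem2 KO) and treatment (DMSO or 25 nM BafA1 for 22 hours), as the labels give them. Per the labels' protocols, marrow of several mice was pooled for each biological replicate, the cells were differentiated with M-CSF, frozen and thawed before treatment, and libraries were made with a 3′ mRNA kit that adds unique molecular identifiers for the removal of PCR duplicates. The step that removed duplicates, the annotation and the version of the quantifier are not given in the sources used here. Per the submitters' processing notes, Salmon and the mouse assembly GRCm39 were used. A 3′ tag counts transcripts at their ends, so values do not depend on gene length, and a deletion elsewhere in a gene can leave its tag in place.

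The deposited table of estimated counts per gene, with 56980 features, holds values that are not normalized, and 42.0% of its values above 0 were not whole (tolerance 1e-06). The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The design had assumed whole counts, so the estimated counts were rounded to whole numbers. A second deposited table holds log2 CPM (counts scaled to library size) made by the authors. TMM-normalized log2 CPM with a prior count of 2, recomputed from the estimated counts, differed from it by at most 0.00045, and it was not used for tests. Symbols came from the deposited gene table, where 148 features repeat the symbol entry of an earlier feature. Totals lay between 4407466 and 7074860 per library, and precision for genes with low counts is limited by counting error. Replicates of a group were compared in pairs by a chi-square over genes, and none agreed within sampling noise (2.27 to 6.22 per degree of freedom).

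Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), which left 12052, and were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, quasi-likelihood test, all 12 libraries in 1 fit with a mean per group and no block). Standard errors of log2 fold changes were derived from the fitted value and its F statistic. Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05 and no fold limit. The contrasts were BafA1 against DMSO in each genotype, Trem2 KO against WT in each treatment, and the difference of the responses. CPM values use TMM library sizes, and means ± SD are over 3 libraries. RNA integrity numbers lay between 9.7 and 9.9 per the labels. The common biological coefficient of variation was 0.080.

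Of 36 gene lists 30 had at least 3 tested members and were tested. Lists were tested with camera (limma 3.58.1, preset correlation 0.01, adjusted over the lists of a contrast), again with an estimated correlation, and with fry. Named genes followed a rule, which took in each contrast the 8 largest increases and 8 largest decreases past the threshold with a mean of at least 20 CPM in the higher group and no overlap between libraries (no overlap condition for the interaction), with predicted genes left out. It also took the 3 members with the smallest p in the direction of each called list and a panel of 12 macrophage, lipid and lysosome genes, of which 1, Cst7, was not tested. A gene of that rule may be named in any comparison.

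Alternatives were other normalizations (RLE factors, upper-quartile factors, library size alone), DESeq2 1.42.0, limma-voom, no filter, a filter of 10 CPM in 3 libraries, only the 6 libraries compared, a 2-fold limit, a replicate block and leaving out each library. The test was tried on simulated data with the means, dispersions and library sizes of these libraries and 200 changed genes among 12052. For BafA1 in WT it recovered 61.2% of 1.5-fold, 79.1% of 2-fold and 95.5% of 4-fold changes, and for the interaction 13.4%, 61.2% and 89.4%. False calls made up 7.10% of calls in the first of these and 6.03% in the second, and the highest share over the 5 contrasts was 8.59%, above the nominal level. Fewer genes were changed than passed in any real contrast, so these shares need not hold for the real tests. Neighbours of Trem2 were tested genes whose start lay within 5 Mb on either side in a RefSeq table of another assembly, GRCm38.p6. In it 11342 of 12039 tested symbols were found, and no coordinates are given.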

Results

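Gene expression was measured in mouse bone-marrow-derived macrophages, which are cells grown out of marrow with the growth factor M-CSF. The cells were wild type (WT) or carried a knockout of Trem2 (Trem2 KO), a lipid-sensing receptor of macrophages and microglia. Cells of each genotype received 25 nM bafilomycin A1 (BafA1), an inhibitor of the proton pump (V-ATPase) that acidifies lysosomes, or the solvent DMSO for 22 hours. Each of the 4 groups held 3 libraries, which the labels call biological replicates from pooled bones of several mice, and the series asks how both genotypes respond to a loss of lysosomal acidity. Libraries held between 4407466 and 7074860 estimated counts, made from 3′ ends of mRNA with molecular identifiers, and 12052 genes were tested. Libraries separated by treatment along the first principal component (47.7% of variance) and by genotype along the second (24.8%).

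**Figure D1:**
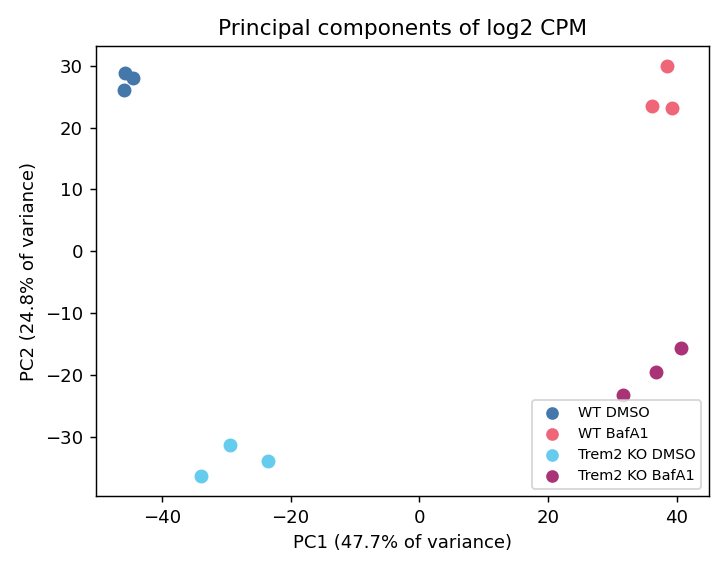
Principal components of the log2 CPM values, PC1 on the x axis and PC2 on the y axis, 1 point per library and 3 libraries per group. BafA1 libraries lie at PC1 values between 31.7 and 40.6 and DMSO libraries between -45.9 and -23.5.

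Trem2 (ENSMUSG00000023992), the targeted gene, was lower in all 6 Trem2 KO libraries than in any WT library, but it was not absent. Its mean was 588 CPM ± 27.2 (SD, n = 3) in WT DMSO, 401 ± 0.45 in WT BafA1, 212 ± 11.04 in Trem2 KO DMSO and 160 ± 19.5 in Trem2 KO BafA1. The KO groups therefore held 36.0% of the WT level in DMSO and 39.8% in BafA1. The log2 difference was -1.47 (SE 0.080) in DMSO and -1.33 (SE 0.081) in BafA1, with edgeR adjusted p of 6.9e-12 and 1.4e-10. The labels do not give the deleted part of the gene, and a 3′ tag outside it could still be counted, so these values neither check the genotype labels fully nor measure how much intact transcript remained. BafA1 lowered the Trem2 count in both genotypes, with a log2 change of -0.55 (SE 0.077) in WT and -0.41 (SE 0.082) in Trem2 KO.

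**Figure D2:**
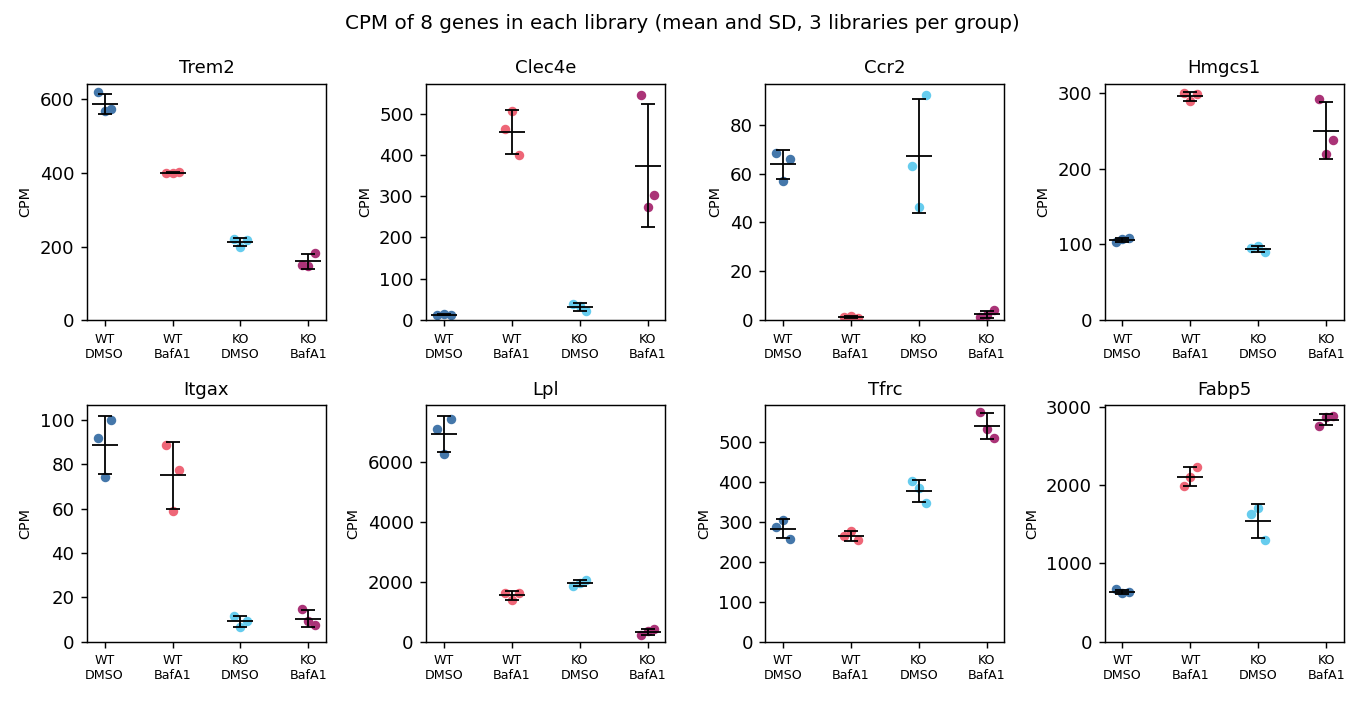
CPM on linear axes that start at 0 for 8 genes, with 1 point per library, the group mean as a bar and its SD as whiskers (3 libraries per group). Trem2 fell from 588 to 401 CPM in WT with BafA1, and all 6 KO libraries lie below the WT libraries.

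The first comparison asked what BafA1 did in WT macrophages, and log2 fold changes are given with their standard errors. Genes of cholesterol synthesis rose together, with all 24 tested members of the cholesterol and SREBP2 list higher (median log2 fold change 1.56), among them Mvd (3.55, SE 0.18), Insig1 (2.40, SE 0.14) and Hmgcs1 (1.48, SE 0.088), which encodes the synthase upstream of HMG-CoA reductase. That list had camera p 5.4e-21, estimated-correlation p 0.051 by camera, where the first p uses a preset correlation between genes and the second an estimated one, both adjusted over the 30 lists. Every one of the 18 endoplasmic reticulum (ER) chaperone and unfolded protein response genes also rose (median 1.32, camera p 8.6e-22, estimated-correlation p 0.037), among them Hspa5, the chaperone BiP, from 957 CPM ± 30.6 to 3300 ± 67.8 (n = 3 each). In the opposite direction, all 30 cell cycle genes fell (median -2.31, camera p 3.5e-32, estimated-correlation p 0.0011), with Top2a, a DNA topoisomerase of dividing cells, at 172 CPM ± 13.9 in DMSO and 34.3 ± 4.21 in BafA1. The chemokine receptors Ccr3 (-6.61, SE 0.28) and Ccr2 (-5.53, SE 0.30) fell steeply, while the C-type lectin receptor Clec4e rose from 13.2 CPM ± 1.46 to 456 ± 53.5.

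Of 18 subunit genes of the V-ATPase, the drug's target, 15 rose and 0 fell (median 0.67, camera p 5.8e-11, estimated-correlation p 0.037), with Atp6v1g1 at 1.24 (SE 0.076) and Atp6v1d at 0.97 (SE 0.071). Lysosomal membrane and transport proteins rose in 18 of 25 and fell in 1 (camera p 3.9e-07, estimated-correlation p 0.044), as in Clcn7, a chloride-proton exchanger (1.23, SE 0.10). Lysosomal hydrolases went both ways, with 20 of 43 higher and 13 lower (camera p 0.0014, estimated-correlation p 0.22), and Naglu (1.71, SE 0.10) and Ctsz (1.31, SE 0.081) among the higher ones. Autophagy genes rose in 17 of 26 and fell in 1 (camera p 0.00013, estimated-correlation p 0.058), among them the autophagy receptors Sqstm1 (0.96, SE 0.074) and Optn (1.86, SE 0.19). Among MiT-TFE factors and nutrient-sensing genes 6 of 10 rose and 3 fell (camera p 0.0028, estimated-correlation p 0.037), and Rragd, a Rag GTPase, rose by 2.12 (SE 0.11).

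ATF4 and stress response genes rose in 19 of 24 and fell in 1 (camera p 1.8e-09, estimated-correlation p 0.058), with Atf4 at 1.58 (SE 0.10) and Ddit3, the transcription factor CHOP, at 1.91 (SE 0.14). Glycolysis genes rose in 15 of 16 (camera p 5.8e-11, estimated-correlation p 0.055), with the lactate transporter Slc16a3 at 1.94 (SE 0.12). HIF targets outside glycolysis rose in 12 of 15 (camera p 1.3e-07, estimated-correlation p 0.035), with the ER oxidase Ero1a at 1.45 (SE 0.097). Fatty acid synthesis genes rose in 8 of 12 (camera p 0.0023, estimated-correlation p 0.23), led by Fasn, fatty acid synthase (2.11, SE 0.14). Inflammatory NF-kB targets rose in 10 of 18 and fell in 3 (camera p 0.038, estimated-correlation p 0.21), such as Sod2, mitochondrial superoxide dismutase (1.45, SE 0.11).

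Complement genes fell in 7 of 9 and rose in 2 (median -2.29, camera p 3.2e-12, estimated-correlation p 0.024), and C1qa went from 285 CPM ± 36.4 to 40.9 ± 0.59. Macrophage identity genes fell in 16 of 19 and rose in 1 (camera p 1.2e-12, estimated-correlation p 0.013), including the Fc receptor gene Fcgr1 (-3.97, SE 0.20) and the transcription factor Maf (-2.38, SE 0.12). Phagocytic and scavenger receptors fell in 15 of 18 and rose in 2 (camera p 3.7e-08, estimated-correlation p 0.035), including the integrin Itgav (-1.77, SE 0.086). LXR targets fell in 7 of 10 (camera p 3.9e-06, estimated-correlation p 0.03), among them the cholesterol exporter Abca1 (-1.88, SE 0.088). Interferon-stimulated genes fell in 22 of 26 and rose in 1 (median -1.15, camera p 7.2e-06, estimated-correlation p 0.21), including Rtp4 (-2.16, SE 0.18) and Oasl2 (-1.80, SE 0.16). Granulocyte markers moved with these lists, since 7 of 7 fell (median -2.53, camera p 0.00015, estimated-correlation p 0.16) and S100a9 went from 44.9 CPM ± 2.49 to 7.79 ± 0.17. Lpl, a secreted lipase, fell from 6911 CPM ± 595 to 1544 ± 144, whereas Gpnmb, a glycoprotein of lysosomes and melanosomes, rose from 4834 ± 265 to 11149 ± 526.

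By edgeR's quasi-likelihood test 5657 genes passed an adjusted p of 0.05 in WT, 2609 higher and 3048 lower, and with a further 2-fold limit 1843 did, 617 higher and 1226 lower. Camera called 19 of 30 lists and 10 kept their call with an estimated correlation. The NF-kB call was lost without WT DMSO replicate 2 (camera p 0.059, median 0.45) or replicate 3 (camera p 0.054, median 0.70). Adjusted over the list alone, 20 lysosomal membrane and transport, 22 ATF4 and 24 interferon-stimulated genes passed, and the other called lists had the same counts as over all genes.

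The second comparison asked the same question in Trem2 KO macrophages. Cholesterol genes rose in 20 of 24 (median 1.75, camera p 1.1e-22, estimated-correlation p 0.068), with Mvd at 3.02 (SE 0.20), Idi1 at 2.54 (SE 0.23) and Insig1 at 2.44 (SE 0.16). ER chaperone genes rose in 17 of 18 (median 0.86, camera p 2.9e-13, estimated-correlation p 0.085), and Hspa5 went from 1003 CPM ± 99.4 to 2198 ± 328 (n = 3 each). Complement genes fell in 7 of 9 and rose in 1 (camera p 8e-18, estimated-correlation p 0.0092), with C1qa going from 513 CPM ± 46.5 to 107 ± 5.69. Macrophage identity genes fell in 17 of 19 and rose in 1 (camera p 4.6e-21, estimated-correlation p 0.005), with Fcgr1 at -3.84 (SE 0.18). Interferon-stimulated genes fell in 25 of 26 (median -1.47, camera p 8.5e-15, estimated-correlation p 0.072). Granulocyte markers again moved with these lists, 7 of 7 lower (median -3.30, camera p 2.6e-13, estimated-correlation p 0.031), with S100a9 at 176 CPM ± 54.9 in DMSO and 25.0 ± 9.59 in BafA1.

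V-ATPase subunits rose in 13 of 18 and fell in 2 in Trem2 KO (camera p 1e-06, estimated-correlation p 0.085), with Atp6v1f at 0.96 (SE 0.075). Lysosomal membrane and transport proteins rose in 14 of 25 and fell in 1 (camera p 0.00049, estimated-correlation p 0.12), with Npc2, a soluble sterol-binding protein of the lysosome, at 0.54 (SE 0.074). Glycolysis genes rose in 14 of 16 (camera p 2.9e-13, estimated-correlation p 0.062), with Ldha, lactate dehydrogenase A, at 1.19 (SE 0.084). HIF targets rose in 11 of 15 and fell in 1 (camera p 1.1e-07, estimated-correlation p 0.031), with Pdk1 at 1.63 (SE 0.11). ATF4 genes rose in 17 of 24 and fell in 1 (camera p 5.8e-08, estimated-correlation p 0.085), with Asns, asparagine synthetase, at 1.87 (SE 0.15). Fatty acid synthesis genes rose in 5 of 12 (camera p 0.016, estimated-correlation p 0.37), and the adenylate kinase gene Ak4 rose by 3.85 (SE 0.25). LXR targets fell in 8 of 10 and rose in 1 (camera p 8.7e-10, estimated-correlation p 0.0092), with Abca1 at -2.02 (SE 0.087). Phagocytic and scavenger receptors fell in 13 of 18 and rose in 2 (camera p 5e-09, estimated-correlation p 0.031), with the scavenger receptor Stab1 at -2.25 (SE 0.13). MHC class II genes fell in 5 of 7 (camera p 0.0015, estimated-correlation p 0.17), and H2-Eb1 went from 42.7 CPM ± 3.21 to 16.2 ± 0.82. Mitochondrially encoded transcripts fell in 8 of 13 (camera p 0.036, estimated-correlation p 0.49), among them mt-Co1 (-0.43, SE 0.074). All features of the mitochondrial genome, its ribosomal and transfer RNA included, made up 4.03% ± 0.27 of counts in the 6 BafA1 libraries of both genotypes and 5.63% ± 1.26 in the 6 DMSO libraries (two-sided exact permutation p = 0.0065, adjusted p = 0.039 over 12 tests of library measures). Cell cycle genes fell in 12 of 30 and rose in 0 (median -0.50), and camera did not call that list (camera p 0.052, estimated-correlation p 0.36). It did with library size alone as the scaling (camera p 0.044), or without WT BafA1 replicate 2 (0.0498), KO DMSO replicate 2 (0.028), KO BafA1 replicate 1 (0.0497) or KO BafA1 replicate 3 (0.045), so this outcome depends on these choices. Hydrolases rose in 19 of 43 and fell in 10 (camera p 0.11), autophagy genes rose in 8 of 26 and fell in 2 (0.077), MiT-TFE genes rose in 4 of 10 and fell in 1 (0.072), and NF-kB targets rose in 5 of 18 and fell in 5 (0.41), so camera called none of these 4 lists in KO. Without KO DMSO replicate 2 or KO BafA1 replicate 1 it called autophagy (medians 0.19 and 0.17) and MiT-TFE genes (0.16 and 0.14). Ccr3 (-5.89, SE 0.33) and Ccr2 (-4.91, SE 0.28) fell here too.

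In Trem2 KO 4888 genes passed in edgeR, 2392 higher and 2496 lower, and 1256 with the 2-fold limit, 390 higher and 866 lower. Without that limit the majority turned with upper-quartile factors (2493 higher, 2407 lower), library size alone (2418, 2347), no filter (2431, 2084) or without KO DMSO replicate 1 (2174, 2115). Camera called 16 of 30 lists and 6 kept their call with an estimated correlation. The mitochondrial call was lost without KO DMSO replicate 1 (camera p 0.13, median -0.19), KO BafA1 replicate 2 (0.051, -0.28) or KO BafA1 replicate 3 (0.076, -0.22). Adjusted over the list alone, 16 lysosomal membrane and transport, 18 ER chaperone, 16 glycolysis, 19 macrophage identity and, in the uncalled cell cycle list, 13 genes passed, and the other called lists had the same counts as over all genes.

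**Figure D3:**
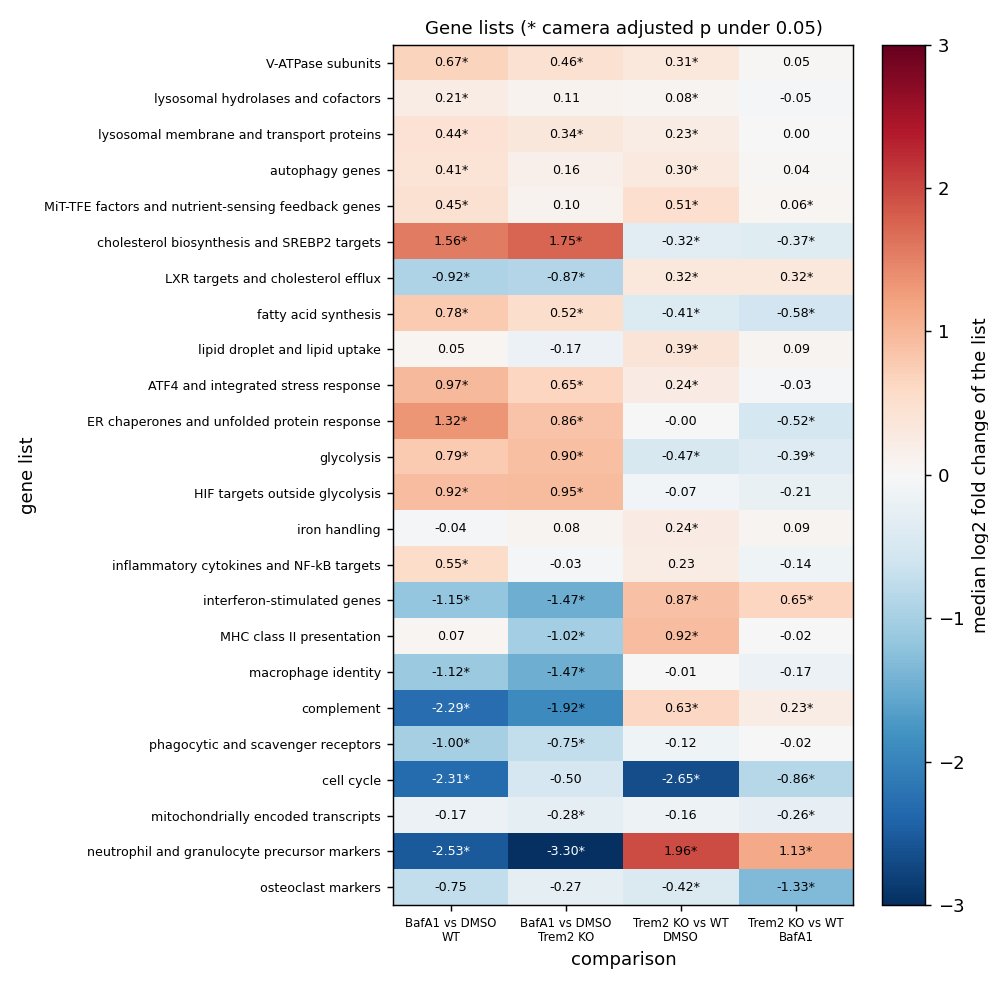
Median log2 fold change of each gene list (vertical axis) in each comparison (horizontal axis), on a colour scale from -3 to 3, for lists that camera called in at least 1 of the 5 contrasts. Asterisks mark camera adjusted p under 0.05 with the preset correlation, and the cell cycle list runs from -2.65 for KO against WT in DMSO to -0.50 for BafA1 against DMSO in Trem2 KO. The difference of the responses is not drawn.

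The third comparison asked how Trem2 KO macrophages differed from WT ones without the drug. All 30 cell cycle genes were lower in KO (median -2.65, camera p 5.4e-75, estimated-correlation p 0.00013), with Top2a at 16.5 CPM ± 2.95 against 172 ± 13.9 in WT (n = 3 each), Birc5, survivin, at -4.05 (SE 0.16) and Ccna2, cyclin A2, at -4.83 (SE 0.31). Interferon-stimulated genes were higher in 23 of 26 (median 0.87, camera p 4.6e-14, estimated-correlation p 0.11), among them Irf7 (1.84, SE 0.21) and Ifi44 (2.92, SE 0.32). MHC class II genes were higher in 4 of 7 (camera p 0.00099, estimated-correlation p 0.28), with H2-Eb1 at 42.7 CPM ± 3.21 against 12.02 ± 0.27. Granulocyte markers were higher beside these lists, 7 of 7 with a median of 1.96 (camera p 1.1e-08, estimated-correlation p 0.11), and S100a9 stood at 176 CPM ± 54.9 against 44.9 ± 2.49. The integrin gene Itgax, which encodes CD11c, was at 9.30 CPM ± 2.46 against 88.6 ± 13.1, and Lpl at 1957 ± 93.4 against 6911 ± 595.

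Among lysosomal lists, V-ATPase subunits were higher in KO in 11 of 18 and lower in 2 (median 0.31, camera p 0.00074, estimated-correlation p 0.29). Hydrolases were higher in 18 of 43 and lower in 8 (camera p 0.018, estimated-correlation p 0.39), and lysosomal membrane and transport proteins higher in 13 of 25 and lower in 2 (camera p 0.0017, estimated-correlation p 0.28). Autophagy genes were higher in 14 of 26 and lower in 2 (camera p 0.0042, estimated-correlation p 0.28). MiT-TFE and nutrient-sensing genes were higher in 7 of 10 and lower in 2 (camera p 0.00031, estimated-correlation p 0.042), with Rragd at 1.59 (SE 0.12) and Flcn, folliculin, at 1.02 (SE 0.10). LXR targets were higher in 7 of 10 (camera p 0.00057, estimated-correlation p 0.11), with the sterol transporter Abcg1 at 0.92 (SE 0.13). Cholesterol genes were lower in 7 of 24 (camera p 0.0089, estimated-correlation p 0.54). Fatty acid synthesis genes were lower in 6 of 12 (camera p 0.022, estimated-correlation p 0.41). Glycolysis genes were lower in 11 of 16 and higher in 2 (camera p 0.00057, estimated-correlation p 0.29), with Gpi1 at -0.89 (SE 0.094). Lipid droplet and uptake genes were higher in 7 of 14 and lower in 2 (camera p 0.014, estimated-correlation p 0.29), with the fatty acid binding protein Fabp5 at 1.27 (SE 0.088). ATF4 genes were higher in 9 of 24 and lower in 5 (camera p 0.031, estimated-correlation p 0.46), with the secreted stress factor Gdf15 at 357 CPM ± 121 against 56.7 ± 8.41. Complement genes were higher in 6 of 9 and lower in 2 (camera p 0.0097, estimated-correlation p 0.29), with C1qa at 0.85 (SE 0.087). Iron genes were higher in 4 of 13 and lower in 2 (camera p 0.021, estimated-correlation p 0.28), with the iron exporter Slc40a1 at 1.60 (SE 0.16). Osteoclast markers were lower in 2 of 7 and higher in 1 (camera p 0.049, estimated-correlation p 0.29), with the fusion protein gene Dcstamp at -3.14 (SE 0.27). Ly6a rose to 21.2 CPM ± 7.06 from 0.64 ± 0.20, a log2 difference of 5.01 (SE 0.37).

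The edgeR test passed 3649 genes, 1666 higher and 1983 lower in KO, and 906 with the 2-fold limit, 329 higher and 577 lower. Camera called 18 of 30 lists and 2 kept their call with an estimated correlation, cell cycle and MiT-TFE genes. The hydrolase call was lost without WT DMSO replicate 3 (median 0.059), the ATF4 call without WT DMSO replicate 3 (0.20) or KO DMSO replicate 2 (0.18). The osteoclast call was lost without WT DMSO replicate 2 (median -0.47), KO DMSO replicate 2 (-0.45) or replicate 3 (-0.26), or KO BafA1 replicate 1 (-0.41). Camera called mitochondrial transcripts only without KO DMSO replicate 1 (median -0.27) and NF-kB targets only without KO DMSO replicate 3 (0.14). Adjusted over the list alone, 15 V-ATPase, 27 hydrolase, 17 lysosomal membrane and transport, 17 autophagy, 9 cholesterol, 7 fatty acid synthesis, 11 lipid droplet, 15 ATF4, 10 iron, 24 interferon-stimulated and 9 complement genes passed, and the other called lists had the same counts as over all genes. The 10 most abundant genes held 17.9% ± 1.83 of counts in the 6 KO libraries of both treatments and 14.3% ± 0.82 in the 6 WT libraries (two-sided exact permutation p = 0.0022, adjusted p = 0.026 over 12 tests). In DMSO features of the mitochondrial genome held 6.67% ± 0.83 of counts in KO and 4.60% ± 0.31 in WT, and ribosomal protein genes 4.63% ± 0.21 and 5.76% ± 0.34 (n = 3 each). Both shares differed without overlap between the libraries of the genotypes. The list of 13 mitochondrially encoded transcripts did not follow the higher share, with 4 lower and 1 higher in KO (median -0.16, camera p 0.23).

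The fourth comparison set the genotypes side by side under BafA1. ER chaperone genes were lower in KO in 15 of 18 (median -0.52, camera p 8.8e-10, estimated-correlation p 0.19), with Sdf2l1 at -1.11 (SE 0.12) and Hspa5 at 2198 CPM ± 328 against 3300 ± 67.8 in WT (n = 3 each). Glycolysis genes were lower in 10 of 16 (camera p 1.8e-07, estimated-correlation p 0.19), with Gapdh at -0.81 (SE 0.10). Cholesterol genes were lower in 14 of 24 (camera p 3.3e-07, estimated-correlation p 0.37), with the regulator Srebf2 at -0.62 (SE 0.094). Fatty acid synthesis genes were lower in 6 of 12 (camera p 9.1e-06, estimated-correlation p 0.19), with Fasn at -1.17 (SE 0.12). Interferon-stimulated genes were higher in 17 of 26 (median 0.65, camera p 2e-08, estimated-correlation p 0.19), with Irf7 at 1.91 (SE 0.31). Complement genes were higher in 4 of 9 and lower in 2 (camera p 0.0024, estimated-correlation p 0.25), with C1qa at 107 CPM ± 5.69 against 40.9 ± 0.59. Granulocyte markers were higher in 2 of 7 beside them (camera p 0.018, estimated-correlation p 0.41), with S100a9 at 1.63 (SE 0.28).

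Cell cycle genes were lower in KO in 20 of 30 under BafA1 (median -0.86, camera p 3.3e-09, estimated-correlation p 0.16), with Birc5 at -2.55 (SE 0.20). Ccnd1, cyclin D1, was lower by -3.09 (SE 0.16) and Itgax by -2.77 (SE 0.19), whereas the transferrin receptor gene Tfrc was higher, at 540 CPM ± 32.9 against 265 ± 11.9. LXR targets were higher in 6 of 10 (camera p 0.00058, estimated-correlation p 0.19), with Mylip, a ligase that degrades the LDL receptor, at 0.90 (SE 0.13). MiT-TFE genes were higher in 4 of 10 (camera p 0.031, estimated-correlation p 0.19), with Rragd at 0.89 (SE 0.093). Osteoclast markers were lower in 5 of 7 (camera p 0.0032, estimated-correlation p 0.19), with Atp6v0d2 at -0.39 (SE 0.081). Mitochondrially encoded transcripts were lower in 7 of 13 (camera p 0.0014, estimated-correlation p 0.4), with mt-Nd4 at -0.52 (SE 0.072).

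Under BafA1 3223 genes passed in edgeR, 1507 higher and 1716 lower in KO, and 607 with the 2-fold limit, 305 higher and 302 lower. The majority turned with upper-quartile factors (1690 higher, 1581 lower). Camera called 12 of 30 lists and 0 kept their call with an estimated correlation. The MiT-TFE call was lost without KO BafA1 replicate 2 (median 0.080) and the granulocyte call without KO BafA1 replicate 3 (median 0.45). HIF targets were called only without WT BafA1 replicate 1 (median -0.23), KO DMSO replicate 2 (-0.21) or KO BafA1 replicate 1 (-0.36). Adjusted over the list alone, 15 cholesterol, 7 LXR, 7 fatty acid synthesis, 16 ER chaperone, 19 interferon-stimulated, 7 complement, 21 cell cycle, 8 mitochondrial, 3 granulocyte and 6 osteoclast genes passed, and MiT-TFE and glycolysis genes had the same counts as over all genes.

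The last comparison asked whether the response to BafA1 differed between the genotypes, with differences given as the KO response minus the WT response on the log2 scale. The cell cycle difference was positive for all 30 genes and passed for 22 (median 1.63, camera p 2.6e-31, estimated-correlation p 0.0018), with Top2a at 1.62 (SE 0.20), the replication helicase gene Mcm7 at 1.73 (SE 0.20) and Cenpf at 2.64 (SE 0.35). The ER chaperone difference was negative for all 18 genes and passed for 7 (median -0.42, camera p 5.9e-09, estimated-correlation p 0.23), with Hspa5 at -0.65 (SE 0.13). The MHC class II difference was negative for all 7 genes and passed for 3 (median -0.98, camera p 1.6e-05, estimated-correlation p 0.19), with H2-Eb1 at -1.44 (SE 0.20), which stood at 12.02 and 12.5 CPM in WT and went from 42.7 to 16.2 CPM in KO. Dio2, the type 2 deiodinase gene, went from 29.6 CPM ± 5.24 to 321 ± 20.0 in WT and from 144 ± 41.7 to 253 ± 65.0 in KO (n = 3 each), a difference of -2.62 (SE 0.24).

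Negative differences passed for 6 of 18 V-ATPase genes (camera p 2.8e-05, estimated-correlation p 0.23), with Atp6v1d at -0.49 (SE 0.10). Among 43 hydrolases 8 negative and 1 positive difference passed (camera p 0.0025, estimated-correlation p 0.36), with Ctsz at -0.66 (SE 0.11). Negative differences passed for 4 of 25 lysosomal membrane and transport genes (camera p 0.00045, estimated-correlation p 0.23), with Clcn7 at -0.78 (SE 0.15), and for 5 of 26 autophagy genes (camera p 0.00015, estimated-correlation p 0.19), with Sqstm1 at -0.45 (SE 0.10). Of 10 MiT-TFE genes 5 passed with a negative difference (camera p 0.0098, estimated-correlation p 0.19), with Rragd at -0.71 (SE 0.15). Negative differences also passed for 4 of 14 lipid droplet genes (camera p 0.003, estimated-correlation p 0.23), with Fabp5 at -0.84 (SE 0.12). Among 24 ATF4 genes 8 passed with a negative and 2 with a positive difference (camera p 0.027, estimated-correlation p 0.65), with Ddit3 at -1.31 (SE 0.18). Of 18 NF-kB targets 3 passed with a negative difference (camera p 0.019, estimated-correlation p 0.23), with the chemokine Ccl3 at -1.62 (SE 0.20). All 7 granulocyte markers had a negative difference and 1 passed (camera p 0.05, estimated-correlation p 0.65), S100a8 at -0.82 (SE 0.22), whose call was lost without WT DMSO replicate 2 (-0.78), WT BafA1 replicate 3 (-0.70) or KO BafA1 replicate 1 (-0.69). Tfrc had a positive difference of 0.61 (SE 0.11). In DMSO camera had called V-ATPase, hydrolase, lysosomal membrane and transport, autophagy, lipid droplet and ATF4 genes higher in KO. Between the genotypes under BafA1 it called none of these lists (camera p 0.93, 0.93, 0.81, 0.93, 0.93 and 0.89 in that order). Atp6v1d went from 196 to 386 CPM in WT and from 321 to 449 in KO. Ctsz went from 298 to 738 CPM in WT and from 395 to 620 in KO.

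The interaction test passed 1062 genes, 588 with a positive and 474 with a negative difference, and 325 with a 2-fold limit, 216 positive and 109 negative. That count is 693 without WT DMSO replicate 2. The majority turned with RLE factors (537 positive, 547 negative), DESeq2 (462, 468), the filter of 10 CPM (548, 555), and without KO BafA1 replicate 1 (469, 488) or 3 (341, 374), while library size alone gave 628 and 376. Across genes, which are not independent replicates, the log2 responses of the genotypes correlated at Pearson 0.742 and Spearman 0.678, and among 3520 genes past the threshold in both, 3448 (98.0%) changed in the same direction. Independent lists of these sizes would share 518 higher and 631 lower genes, and 1622 and 1826 were shared. Camera called 12 of 30 lists and 1, cell cycle, kept its call with an estimated correlation. The granulocyte call was lost in 7 of 12 fits without 1 library, those without WT DMSO replicate 2 (median -0.65) or 3 (-0.84), WT BafA1 replicate 3 (-0.73), KO DMSO replicate 1 (-0.75) or 3 (-0.61), and KO BafA1 replicate 1 (-0.47) or 2 (-0.66). The ATF4 call was lost without WT DMSO replicate 3 (median -0.28), WT BafA1 replicate 2 (-0.34), KO DMSO replicate 2 (-0.31) or KO BafA1 replicate 1 (-0.30), and the NF-kB call without KO DMSO replicate 1 (-0.066). Interferon-stimulated genes were called only without WT BafA1 replicate 1 (median -0.28) or 2 (-0.28), KO DMSO replicate 1 (-0.33), or KO BafA1 replicate 2 (-0.30) or 3 (-0.29). Osteoclast markers were called only without WT BafA1 replicate 2 (-0.49), mitochondrial transcripts without KO DMSO replicate 2 (-0.12) or KO BafA1 replicate 1 (-0.16), and cholesterol genes without KO BafA1 replicate 1 (-0.26). Adjusted over the list alone, 7 V-ATPase, 10 hydrolase, 8 lysosomal membrane and transport, 13 autophagy, 6 MiT-TFE, 5 lipid droplet, 15 ATF4, 15 ER chaperone, 5 MHC class II and 28 cell cycle genes passed, and NF-kB and granulocyte lists had the same counts as over all genes.

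**Figure D4:**
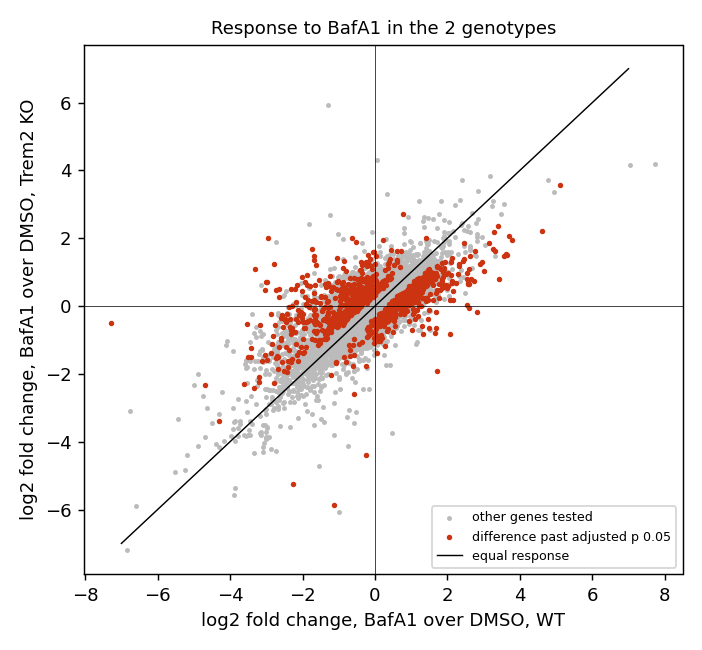
Log2 fold change of BafA1 over DMSO in WT (x axis) and in Trem2 KO (y axis) for the 12052 genes tested, with the line of equal response. Red points are the 1062 genes whose response differed between genotypes at an adjusted p of 0.05.

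**Figure D5:**
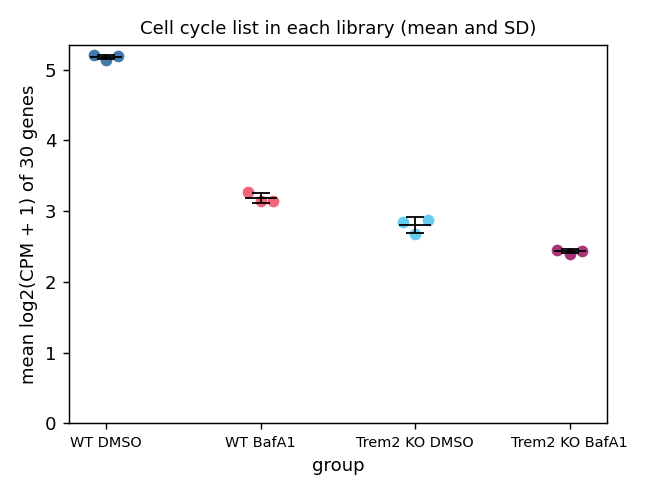
Mean log2(CPM + 1) of the 30 cell cycle genes in each library, with group means as bars and SD as whiskers (3 libraries per group). The group means were 5.18 in WT DMSO, 3.18 in WT BafA1, 2.80 in Trem2 KO DMSO and 2.43 in Trem2 KO BafA1.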

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

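Tests of explanations for Trem2, cell cycle and granulocyte genes below were chosen after those results were seen, and the counts of other splits were planned before, except that the number of splits drawn for the interaction was set after a first count. The lists and genes given first were picked out because the response to BafA1 differed between the genotypes. This was by the interaction test for genes, which passed 1062, or by camera for lists. The Trem2 counts and the granulocyte markers in DMSO, treated further below, were not picked by this rule. Camera called 12 lists, of which cell cycle kept its call with an estimated correlation (adjusted p = 0.0018) and the other 11 lost it (adjusted p from 0.19 to 0.65). The median log2 differences (KO response minus WT response) of the lists were 1.63 for cell cycle, -0.23 for V-ATPase subunits, -0.15 for lysosomal hydrolases, -0.22 for lysosomal membrane and transport proteins, -0.29 for autophagy, -0.23 for MiT-TFE genes, -0.14 for lipid droplet genes, -0.36 for ATF4 genes, -0.42 for ER chaperones, -0.19 for NF-kB targets, -0.98 for MHC class II and -0.71 for granulocyte markers.

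Genes with a positive log2 difference were Ccna2 (2.65), Cenpf (2.64), Mki67 (2.45), Hpgd (2.38), Spc25 (2.31), Uhrf1 (2.19), Prc1 (2.11), Ccnb1 (2.02), Mcm7 (1.73), Tfrc (0.61) and Tyrobp (0.45). Several of these differences rest on low counts. In the KO libraries Ccna2 lay between 0.46 and 1.80 CPM, Uhrf1 between 0.80 and 3.00, Ccnb1 between 0.93 and 3.47 and Mki67 between 3.25 and 5.05. Hpgd lay between 0.17 and 1.85 CPM in WT BafA1. Negative log2 differences were found for Saa3 (-2.68), Dio2 (-2.62), Csf1 (-2.45), Cdkn1c (-2.39), Ccl5 (-2.14), Mgll (-2.08), Gprc5b (-1.98), Pdpn (-1.87), Ccl3 (-1.62), H2-Eb1 (-1.44), Ddit3 (-1.31) and Hilpda (-1.28). Smaller negative differences were those of S100a8 (-0.82), Slc29a3 (-0.80), Atp6v0d2 (-0.69), Ctsz (-0.66), Hspa5 (-0.65), Tax1bp1 (-0.60), Atf4 (-0.59), Fnip2 (-0.59), Spp1 (-0.47) and Gpnmb (-0.39). Some calls were lost when a single library was left out, with the value then found in brackets. This was so for Ccna2 (2.09 without KO BafA1 replicate 2), Ccnb1 (1.45 without KO BafA1 replicate 1) and Uhrf1 (1.55 without KO BafA1 replicate 1). Hpgd lost its call without any 1 of these libraries: WT DMSO replicate 2 2.24, WT BafA1 replicate 2 2.32, WT BafA1 replicate 3 1.92, KO BafA1 replicate 1 2.16, KO BafA1 replicate 3 2.41. Gpnmb lost its call without any 1 of these libraries: WT DMSO replicate 2 -0.35, WT BafA1 replicate 1 -0.38, WT BafA1 replicate 3 -0.36, KO DMSO replicate 2 -0.32, KO BafA1 replicate 1 -0.35, KO BafA1 replicate 3 -0.40. It was also lost with upper-quartile factors (-0.36). Spp1 lost its call without any 1 of these libraries: WT DMSO replicate 2 -0.40, WT BafA1 replicate 3 -0.40, KO DMSO replicate 2 -0.38. Tyrobp lost its call without any 1 of these libraries: WT DMSO replicate 1 0.39, WT DMSO replicate 2 0.45, WT BafA1 replicate 1 0.43, WT BafA1 replicate 2 0.46, KO DMSO replicate 2 0.41, KO BafA1 replicate 3 0.33. S100a8 lost its call without any 1 of these libraries: WT DMSO replicate 2 -0.78, WT BafA1 replicate 3 -0.70, KO BafA1 replicate 1 -0.69. It was also lost in DESeq2 (-0.83).

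Other splits of the libraries were refitted for each count. For each contrast of 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and 1 split, the real one, reached the real count. The real counts were 5657, 4888, 3649 and 3223, and the highest of the other splits gave 0 genes in all 4 contrasts. Every other split mixed libraries of both groups in each arm, so a difference between the groups entered the spread there. These counts of 0 therefore do not argue against chance. For the interaction, 100 of the 200 splits of the genotype labels within treatments were drawn, and 6 of them, the real one included, gave at least 1062 genes, a share of 0.06. The highest other split gave 4754 genes. All 5 other splits as large left the DMSO labels in place and exchanged 4 or 6 of the BafA1 labels, which puts the genotype difference shared by both treatments into the interaction, so they point to the genotype structure of the samples. The share therefore does not measure chance, and this count leaves open whether chance can be excluded. A first draw of 50 of these splits had given 1 as large, a share of 0.02 with a highest other count of 1028, and the number was then raised to 100, so the share depends on which splits were drawn.

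The BafA1 response of cell cycle genes differed between genotypes, with all 30 differences positive and median changes of -2.31 in WT and -0.50 in KO. Compression of fold changes at low counts is argued against as the whole account, because all 7 members with a mean of at least 10 CPM in each group passed, with a median difference of 1.105. It stays open for the other 23 (median 1.73), and the 15 members with the highest mean over all libraries (1.496, against 1.74 in the other 15) decide nothing more, since some of them are low in KO. The lowest WT DMSO library lay 2.26 above the highest KO DMSO library in mean log2(CPM + 1), which restates the genotype difference and tests no batch, and the labels name none. Genotype itself stays open as a biological account, and so does a lower limit of the response in KO cells, whose DMSO mean (2.80) lay below that of WT BafA1 (3.18).

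Trem2 counts in KO libraries stood at 36.0% of the WT level in DMSO and 39.8% in BafA1. WT cells or RNA mixed into the KO libraries, as the only source, would leave every gene at that share or above, yet 28 of 3546 genes with a WT mean of at least 50 CPM lay below it in DMSO by more than 2 standard errors of each value, and 6 did so in both treatments. Reads from a part of the gene outside the deletion may remain, and the lowest KO library held 147 CPM. Counts per gene do not show which exons the reads come from, so that stays open.

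Granulocyte markers were higher in Trem2 KO in DMSO, by log2 differences from 0.76 (Mmp8) to 2.29 (Lcn2). A larger share of granulocytes with the same marker levels in both genotypes, as the only source, would raise every marker by a common fold. Granulocytes whose marker levels differ between the genotypes could give unequal folds, so the test below cannot decide on them. Cochran's Q, a chi-square test on the edgeR estimates that treats the standard errors as known and the markers as independent, found that the folds differed (p = 2.7e-07). A share of granulocytes may still contribute to these folds, as may expression in the macrophages, and the most abundant markers, S100a8 and S100a9, reached 242 and 176 CPM.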

How the results depend on the processing

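Directions held as far as they were compared: no gene called in both the main fit and an alternative changed sign. No called list and no called gene among the named ones changed sign either. Other genes that lost their call were not compared. With the 2-fold limit the counts were 1843 and 1256 for BafA1 in WT and KO, 906 and 607 for genotype in DMSO and BafA1, and 325 for the interaction, by construction of that limit. With an estimated correlation the number of called lists was 10, 6, 2, 0 and 1 in the same order. For BafA1 in WT the estimate was 0.54 for cholesterol and 0.37 for glycolysis genes, which lost their calls, against the preset of 0.01. The preset p values of such lists therefore assume far less correlation between members than was estimated. MiT-TFE genes lost their call between genotypes in BafA1 although their estimate, -0.018, lay below the preset. What else lowered the calls was not tested. The correlation of the responses rose to 0.834 with the filter of 10 CPM, where fewer genes were tested. Leaving out 1 library at a time gave 4979 to 5730 genes for BafA1 in WT, 4116 to 4952 in KO, 3030 to 3726 for genotype in DMSO, 2165 to 3324 in BafA1 and 693 to 1200 for the interaction. Lists called ranged from 18 to 19, 15 to 19, 16 to 19, 11 to 13 and 10 to 13 in these fits. The lowest interaction count, 693 without WT DMSO replicate 2, kept 677 of the 1062 genes. DESeq2 gave 5054, 4289, 3148, 2671 and 930 genes, and 865 of its interaction genes were among the 1062.

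The replicate block gave 5940, 5155, 3640, 3225 and 1481 genes and kept all 77 called lists. Replicate numbers were not treated as pairs, because the labels do not say whether they pair DMSO and BafA1 cultures. Same-numbered WT libraries deviated together with correlations of -0.0051, 0.043 and 0.061, and KO libraries with 0.074, 0.16 and 0.12. KO libraries and WT replicates 2 and 3 correlated best with their own number, while WT replicate 1 did not. Between the genotypes same-numbered correlations lay between -0.10 and 0.046. With the block the interaction count went from 1062 to 1481, so a pairing within genotype stays open. Of simulated 1.5-fold changes 13.4% were recovered in the interaction and 44.8% to 61.2% in the other contrasts.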

Other observations

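The grouping of ERK target genes was noticed in the data from its first 3 genes, and the test on further members was written before their values were seen. Camera called 6 lists in none of the 5 contrasts. Of 24 disease-associated microglia genes 11 rose and 12 fell with BafA1 in WT (camera p 0.82), and 9 were higher and 9 lower in Trem2 KO in DMSO (camera p 0.92). Spp1, osteopontin, rose from 1150 CPM ± 94.3 to 2298 ± 192 in WT and from 1367 ± 139 to 1974 ± 127 in Trem2 KO, and Apoe, apolipoprotein E, fell from 2487 ± 23.5 to 1385 ± 148 in WT and from 3924 ± 590 to 2408 ± 765 in Trem2 KO. Of 15 p53 targets 5 rose and 4 fell with BafA1 in WT (camera p 0.87), of 15 NRF2 targets 2 rose and 5 fell (camera p 0.70), of 23 nuclear-encoded respiratory chain genes 5 rose and 0 fell (camera p 0.45), of 3 dendritic cell markers 0 rose and 2 fell (camera p 0.46), and of 5 Trem2 signalling partners 1 rose and 2 fell (camera p 0.49).

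Ccnd1, Etv5 and Dusp6, which are known targets of ERK signalling, were lower in Trem2 KO in both treatments, by log2 differences of -2.59 (SE 0.12), -2.45 (SE 0.15) and -1.85 (SE 0.15) in DMSO and -3.09 (SE 0.16), -2.92 (SE 0.20) and -2.70 (SE 0.18) in BafA1. A hypothesis is that ERK target genes were lower as a group. Of 7 further genes of a known ERK target signature, Phlda1, Spry2 and Dusp4 were expressed enough to test. All 3 were lower in DMSO (median -0.88). In BafA1 the median of all 3 was -1.08, and Spry2 and Dusp4 passed while Phlda1 stood at -1.02 with an edgeR adjusted p of 0.063. The higher of both fry p values was 3.1e-05. The medians and p values met what was predicted for lower ERK targets as a group. Fry asks only whether the set itself changed, and 30.3% of all genes tested passed in DMSO and 26.7% in BafA1. The set was not compared with other genes, so this p does not show a shift particular to ERK targets. The result covers these genes only, and ERK activity was not measured.

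Rn18s-rs5, a ribosomal RNA feature, was the most abundant in every library, at 4.81% to 8.80% of counts. Among 61 tested genes within 5 Mb of Trem2 in GRCm38, 15 differed between genotypes in DMSO (24.6%, against 31.2% of other genes, Fisher's exact p = 0.33) and 18 in BafA1 (29.5% against 27.3%, Fisher's exact p = 0.67).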
